A study of Stenocereus queretaroensis with 6 samples.

How the data were processed

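Gene expression was measured by RNA sequencing in 6 libraries of *Stenocereus queretaroensis* suspension cells, 3 from MS medium with 3% sucrose and 3 from MS medium with 8% sucrose. Each library was placed in its group by the growth medium in its label. Per the labels' protocols, RNA was extracted with TRIzol and column purification, poly(A) RNA was captured on oligo-dT beads, libraries were made with the NEBNext Ultra RNA kit, and they were sequenced as read pairs on a NovaSeq instrument. The NEBNext Ultra kit does not mark strand, so reads of a gene and of an antisense partner cannot be told apart.

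The deposited table has 1 row per assembled transcript cluster, 170970 in all. Per the submitters' processing notes, FastQC, Trimmomatic 0.36, Bowtie2 and RSEM were used. The series title says that the transcriptome was assembled de novo. The assembler, the clustering tool, the versions of the annotation databases and the differential test are not given in the sources used here. Per the file headers, the authors deposited a read count per cluster and library, which is an expected count of the kind RSEM estimates, since 45.4% of the values are not whole. The authors also deposited FPKM per library (fragments scaled by cluster length and library size, per the file headers), which no test here used, because the counts fit a count model. The authors' log2 ratio of 8% over 3% sucrose and its q-value, per the file headers, were used only to count the authors' calls. The deposited log2 ratio is missing for 9914 clusters, minus infinity for 12284 and plus infinity for 17902. The file headers also give the cluster length, from 201 to 15505 bp with a median of 1077 bp, and best hits in the NR and Swiss-Prot protein databases with their E-values, all as other deposited values. An NR hit was present for 100727 clusters, which hold 93.75% of the counts. A Swiss-Prot hit was present for 76970 clusters, which hold 83.21% of the counts, and these fall on 17079 distinct proteins. Several clusters therefore share a protein hit. Reads of one gene, of its alleles or of near-identical gene copies can be divided between such clusters, so a single cluster's change is uncertain where other clusters share its hit.

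Expected counts were rounded to whole numbers. Clusters with too few counts were removed with edgeR's filterByExpr, which left 85043 clusters with 99.29% of the counts and removed 85927. Of the tested clusters 2488 had 0 counts in every library at 3% sucrose and 1827 in every library at 8% sucrose. Counts were scaled with TMM factors, which were 0.940, 0.936 and 0.966 at 3% sucrose and 1.056, 1.039 and 1.074 at 8% sucrose. The quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) compared the media with no covariate, with Benjamini-Hochberg adjustment and a threshold of 0.05. The common biological coefficient of variation was 41.4%. CPM are counts scaled to a common library total, on TMM-scaled library sizes, and means are given with the SD over 3 libraries. The SE of a log2 fold change is its size divided by the square root of the quasi-likelihood F statistic. On these library sizes 3 counts, the limit that a count of 0 allows, correspond to 0.0784 to 0.0882 CPM at 3% sucrose and to 0.0776 to 0.0821 CPM at 8% sucrose. Folds against a group at 0 are given as lower bounds against the mean CPM of 3 counts in each library of that group. These bounds cover counting error only. Replicate libraries of a medium differed by more than sampling noise, with chi-square values per cluster of 8.56 to 15.48, so none was counted as a duplicate.

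The 20 gene lists, as patterns on Swiss-Prot descriptions, the tests, the alternatives and the rule for named clusters were fixed before the data were examined. For each list the rule names the member that rose and the member that fell with the smallest adjusted p. It adds the 3 largest rises and 3 largest falls among called clusters with an informative Swiss-Prot description, a mean of at least 100 counts and no overlap between the media, and the 2 most strongly enriched terms in each direction. Values summed over all clusters of a Swiss-Prot hit are shown for hits among the 8 most abundant of each list, for hits of named clusters and for abundant hits of the families in the closing section. They were chosen after the main results had been seen. Lists were tested for a directional change with camera in limma 3.58.1, with a preset inter-gene correlation of 0.01 and adjustment over the 20 lists, and again with the correlation estimated per list. Gene Ontology biological process terms with 20 to 1000 tested clusters were tested against 39635 tested clusters with any such term. Shares of counts by kind of organism were compared with an exact two-sided permutation test, whose smallest p for 3 against 3 is 0.1. Figures were drawn with matplotlib 3.10.9.

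The tests were checked on simulated data with the same 85043 clusters and library sizes, in which 200 clusters were changed. Of 100 clusters changed 2-fold 24% were recovered, and of 100 changed 4-fold 74%. Of 102 clusters called 4 were not changed. The shifted list was called and 0 of 10 unshifted lists were. The simulated clusters varied independently and the lists were drawn at random. This check therefore does not show how often lists of correlated genes are called without a shift.

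The alternatives were size factors and the Wald test from DESeq2 1.42.0, no filter or a stricter one, counts summed by Swiss-Prot hit, other thresholds, only clusters with a land plant hit, lists matched on NR descriptions, an estimated correlation, the fry test, other term sizes, 1 cluster per hit, a stricter E-value, the replicate number as a block, and leaving out each library in turn. KEGG, Pfam and KOG annotations were not analysed here.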

Results

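RNA was sequenced from suspension cells of *Stenocereus queretaroensis*, a columnar cactus grown in Mexico for its fruit. Suspension cells are plant cells that multiply as single cells and small clumps in a shaken liquid medium. The cells were kept on MS medium, a standard mineral medium for plant tissue culture, with either 3% or 8% sucrose as the sugar supply. Each medium had 3 libraries, which makes 6 in all, prepared from poly(A) RNA. The sample titles also carry a letter, Y in every library at 3% sucrose and R in every library at 8% sucrose, and the labels do not say what it stands for. The labels do not say whether the 3 libraries of a medium came from separate cultures, so p-values measure only the spread between these samples, which may be technical. No genome was used here, so transcripts have no chromosome positions. The features are assembled transcript clusters, each identified by its cluster number and named by the description of its best Swiss-Prot protein hit.

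The libraries at 3% sucrose held 36357450, 41147265 and 38023294 expected counts, and those at 8% sucrose held 36919130, 35476032 and 36337686. At least 1 count was found for 118088, 119916 and 121964 clusters at 3% sucrose and for 127521, 127362 and 129537 clusters at 8% sucrose, of 170970 clusters in the assembly. The 10 most abundant clusters took 5.21% to 5.56% of the counts at 3% sucrose and 6.10% to 6.37% at 8% sucrose. Across clusters, which are not independent replicates, log2 CPM (counts scaled to a common library total) of libraries of the same medium correlated with Pearson's r of 0.9625 to 0.9787. Libraries of different media correlated with r of 0.7537 to 0.7769. The first principal component separated the media and held 76.3% of the variance. The second held 6.92% and set replicate 1 at 3% sucrose, with a score of 192.28, apart from the other 5 libraries, which scored between -101.13 and 40.15. The share of counts on 3 clusters resembling ribosomal RNA, with a hit to the yeast protein ART2 that lies antisense to rRNA, was 1.39% ± 0.0941 (SD, n = 3) at 3% sucrose and 0.717% ± 0.275 (SD, n = 3) at 8% sucrose. An exact two-sided permutation test gave p = 0.1 for this share, the smallest p that 3 libraries against 3 allow.

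The comparison of the media asked which transcripts differ between cells on 8% and on 3% sucrose. At 8% sucrose, transcripts of heat shock proteins and of phenylpropanoid and flavonoid biosynthesis were higher. Transcripts of cytosolic ribosomal proteins, photosynthesis, aquaporins, nitrogen assimilation and the betalain and tyrosine pathway were lower. These 7 lists were called with a preset correlation between genes, and with an estimated correlation photosynthesis kept its call and the other 6 lost theirs. The estimate exceeded the preset of 0.01 for ribosomal proteins (0.1393), aquaporins (0.0827), heat shock proteins (0.0587) and nitrogen assimilation (0.0206). It did not for the phenylpropanoid list (0.01), the betalain list (-0.0157) and photosynthesis (-0.0011). For the phenylpropanoid and betalain lists the lost call is therefore not explained by a higher correlation between genes. Photosynthesis, with an estimate under the preset, also went from an adjusted p of 4.57e-06 to 0.0442 in this test (limma's camera). A higher correlation is thus not the only source of the higher p-values with an estimated correlation, and their source was not tested. Of 85043 clusters tested, 24723 rose and 21741 fell at 8% sucrose, and 38579 did not pass the test (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05). The change was at least 2-fold for 21879 of the clusters that rose and for 17077 of those that fell. The median log2 fold change of all tested clusters was 0.19. The values of the 3 libraries of one medium lay wholly above those of the other for 57493 clusters, or 67.6%, where chance gives 10%. The authors' deposited table calls 25353 clusters higher and 23610 lower at 8% sucrose. Of the 46464 clusters called here, 39855 are called in the same direction in the authors' deposited table, 6609 are not called there, and 0 are called in the opposite direction.

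Heat shock proteins, the chaperones that bind unfolded proteins, were higher at 8% sucrose. The pattern of this list also took hits named heat shock factor protein, which are transcription factors and not chaperones. Of 263 tested clusters 177 rose, 34 fell and 52 did not pass the test, and 181 rose and 35 fell when adjusted over the list alone. The summed level of the list was 14120 ± 287 CPM (SD, n = 3) at 3% sucrose and 47730 ± 2650 CPM (SD, n = 3) at 8% sucrose, a ratio of 3.38. A class I small heat shock protein (Cluster-2051.81212) rose from 8.999 ± 0.442 to 511.5 ± 10.9 CPM, with a log2 fold change of 5.83 ± 0.06 (SE) and an adjusted p of 1.51e-07. Summed over all clusters of a hit, heat shock protein 82 rose from 442 ± 13.5 to 4210 ± 409 CPM. The disaggregase ClpB1 rose from 440 ± 10 to 3230 ± 328 CPM, and a chloroplast small heat shock protein from 674 ± 45.7 to 3110 ± 198 CPM. The strongest call among the members that fell was a co-chaperone, Hsp70-Hsp90 organizing protein 2 (Cluster-2051.31396), from 82.24 ± 4.29 to 10.73 ± 0.453 CPM, a log2 fold change of -2.94 against -0.84 for the 7 clusters of this hit together. The hit of the related Hsp70-Hsp90 organizing protein 3 rose from 370 ± 9.61 to 1810 ± 57.8 CPM. The list's median log2 fold change was 1.83 and its directional test (limma's camera with a preset correlation of 0.01) gave an adjusted p of 9.75e-09. The call was lost with adjusted p = 0.181 with an estimated correlation.

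Transcripts of phenylpropanoid and flavonoid biosynthesis, the route from phenylalanine to flavonoids, were higher at 8% sucrose. Of 62 tested clusters 42 rose, 11 fell and 9 did not pass the test, and 44 rose and 12 fell when adjusted over the list alone. The summed level was 1191 ± 26.3 CPM (SD, n = 3) at 3% sucrose and 6616 ± 194 CPM (SD, n = 3) at 8% sucrose, a ratio of 5.55. Flavanone 3-dioxygenase (Cluster-2051.78504), which hydroxylates flavanones to dihydroflavonols, rose from 411.2 ± 3.66 to 3201 ± 65.2 CPM, with a log2 fold change of 2.96 ± 0.04 (SE) and an adjusted p of 2.71e-07. Summed by hit, phenylalanine ammonia-lyase, the entry enzyme of the route, rose from 150 ± 10.5 to 588 ± 72.2 CPM. Chalcone synthase, the first enzyme of the flavonoid branch, rose from 156 ± 8.92 to 1060 ± 75.8 CPM, and 4-coumarate--CoA ligase 2 from 9.43 ± 1.08 to 355 ± 54.4 CPM. A cluster with a naringenin,2-oxoglutarate 3-dioxygenase hit (Cluster-2051.20504) fell from 60.16 ± 2.65 to 7.879 ± 0.348 CPM. The median log2 fold change was 3.12, or 2.94 with the 6 members at 0 at 3% sucrose set to their bound, and the adjusted p was 8.88e-05. The call was lost with adjusted p = 0.133 with an estimated correlation. It was also lost when counts were summed by Swiss-Prot hit, with 15 hits higher and 9 lower of 27, a median log2 fold change of 1.05 and an adjusted p of 0.141.

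Cytosolic ribosomal proteins, the protein part of the ribosomes outside organelles, were lower at 8% sucrose. Of 434 tested clusters 246 fell, 40 rose and 148 did not pass the test, and 254 fell and 41 rose when adjusted over the list alone. Their summed level was 32080 ± 1220 CPM (SD, n = 3) at 3% sucrose and 10760 ± 238 CPM (SD, n = 3) at 8% sucrose, a ratio of 0.335. 40S ribosomal protein S8 (Cluster-2051.74318) fell from 423.8 ± 11.9 to 37.36 ± 1.02 CPM, with a log2 fold change of -3.50 ± 0.05 (SE) and an adjusted p of 3.01e-07. Summed by hit, 60S ribosomal protein L10 fell from 1130 ± 60.8 to 232 ± 5.71 CPM and 60S ribosomal protein L3 from 780 ± 4.48 to 234 ± 9.78 CPM. 40S ribosomal protein S27 (Cluster-2051.84936) went the other way, from 47.28 ± 1.96 to 95.40 ± 4.89 CPM. With counts summed by hit, 123 of 154 ribosomal protein hits fell and 8 rose. The median log2 fold change was -1.23 and the adjusted p was 1.77e-11, which became adjusted p = 0.21 with an estimated correlation. The share of counts on clusters resembling ribosomal RNA was 0.717% at 8% sucrose and 1.39% at 3% sucrose.

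Photosynthesis transcripts were lower at 8% sucrose. Of 99 tested clusters 51 fell, 13 rose and 35 did not pass the test, and 52 fell and 13 rose when adjusted over the list alone. The summed level was 1820 ± 30.6 CPM (SD, n = 3) at 3% sucrose and 645.2 ± 49.2 CPM (SD, n = 3) at 8% sucrose. A chlorophyll a-b binding protein of the light-harvesting antenna (Cluster-2051.124504) fell from 572.9 ± 16.2 to 7.662 ± 0.62 CPM, with a log2 fold change of -6.22 ± 0.08 (SE) and an adjusted p of 2.71e-07. Another antenna protein, chlorophyll a-b binding protein 6, fell from 67.0 ± 2.88 to 7.69 ± 0.366 CPM. A cluster of the photosystem I apoprotein A2 (Cluster-2051.78382), a gene that plants carry in the chloroplast genome, rose from 0.4515 ± 0.243 to 19.24 ± 0.495 CPM, while the 2 clusters of its hit together went from 43.8 ± 1.68 to 83.5 ± 6.3 CPM. The pattern also took 14 clusters of light-harvesting complex-like proteins and of proteins named as factors, of which 1 rose and 6 fell. The median log2 fold change of the list was -1.52 and the adjusted p was 4.57e-06. Of the 7 lists called, this was the 1 list whose call held with an estimated correlation, at an adjusted p of 0.0442.

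Aquaporins, the channels through which water crosses membranes, were lower at 8% sucrose. Of 43 tested clusters 25 fell, 3 rose and 15 did not pass the test, with the same counts when adjusted over the list alone. The vacuolar membrane aquaporin TIP1-1 (Cluster-2051.56731) fell from 965.5 ± 31.2 to 23.89 ± 0.659 CPM, with a log2 fold change of -5.34 ± 0.05 (SE) and an adjusted p of 1.51e-07. Summed by hit, the plasma membrane aquaporin PIP2-1 fell from 367 ± 17.4 to 63.8 ± 3.32 CPM and NIP5-1 from 77.0 ± 1.35 to 6.33 ± 0.717 CPM. Of the 8 most abundant hits 4 changed little, PIP1-4 from 261 ± 7.93 to 237 ± 8.56 CPM, PIP2-2 from 145 ± 3.77 to 121 ± 4.42 CPM, PIP1-3 from 44.9 ± 5.22 to 36.3 ± 3.88 CPM and one PIP2-7 hit from 102 ± 7.62 to 99.9 ± 2.33 CPM, of which the last did not pass the test. A cluster with another PIP2-7 hit (Cluster-19522.0) rose from 0.1929 ± 0.0231 to 1.003 ± 0.121 CPM. The summed level was 2268 ± 74.3 CPM (SD, n = 3) at 3% sucrose and 702.1 ± 7.5 CPM (SD, n = 3) at 8% sucrose, and most of this difference was the TIP1-1 cluster. The list's adjusted p was 8.88e-05, which became adjusted p = 0.21 with an estimated correlation. The number of members that rose was 5 without replicate 1, without replicate 2 or without replicate 3 of the libraries at 3% sucrose.

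The betalain and tyrosine pathway list covers enzymes that make betalains, the red and yellow pigments that cacti form in place of anthocyanins, and enzymes of tyrosine metabolism. Of 31 tested clusters 14 fell, 4 rose and 13 did not pass the test, and 17 fell and 4 rose when adjusted over the list alone. An inactive cytochrome P450 76AD1 (Cluster-2051.22420) fell from 12.3 ± 0.992 to 0.6327 ± 0.0332 CPM, with a log2 fold change of -4.27 ± 0.16 (SE) and an adjusted p of 2.96e-06, and the 4 clusters of its hit together gave -2.7. Summed by hit, DOPA dioxygenase (4,5-DOPA dioxygenase extradiol), which opens the ring of DOPA to form betalamic acid, fell from 159 ± 1.74 to 91.2 ± 7.32 CPM. Another hit of the list, 4,5-DOPA dioxygenase extradiol 1, rose from 3.68 ± 2.32 to 15.2 ± 2.68 CPM. The cytochrome P450 76AD1 hit, which oxidises tyrosine and DOPA, fell from 30.9 ± 1.48 to 25 ± 1.67 CPM, with a log2 fold change of -0.30 ± 0.07 (SE). A tyrosine decarboxylase 1 cluster (Cluster-2051.48689) rose from 0.1664 ± 0.0975 to 1.578 ± 0.246 CPM, a log2 fold change of 3.22 against 1.4 for the 2 clusters of its hit. Another hit with the same name, the most abundant hit of the list, fell from 209 ± 5.23 to 111 ± 3.63 CPM. The list was called lower with an adjusted p of 0.00405, which became adjusted p = 0.14 with an estimated correlation. Without replicate 3 at 3% sucrose, 2 members rose.

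Nitrogen assimilation transcripts were lower at 8% sucrose, with 67 of 173 tested clusters that fell, 32 that rose and 74 that did not pass the test, and with the same counts when adjusted over the list alone. Cytosolic glutamine synthetase 1 (Cluster-2051.126872), which joins ammonium to glutamate, fell from 92.57 ± 2.47 to 0.5593 ± 0.144 CPM, with a log2 fold change of -7.36 ± 0.16 (SE) and an adjusted p of 5.88e-07. Summed by hit, nitrate reductase, the first enzyme of nitrate use, fell from 437 ± 38.9 to 25.7 ± 3.70 CPM and ferredoxin-dependent glutamate synthase from 316 ± 23.6 to 78.0 ± 4.46 CPM. A glutamate dehydrogenase B cluster (Cluster-2051.77664) rose from 50.21 ± 2.88 to 159.1 ± 4.44 CPM, but all 8 clusters of this hit together gave a log2 fold change of -0.14. The pattern also took 52 clusters of folylpolyglutamate synthase and of transporters named for peptides and nitrate, of which 16 rose and 14 fell. The list's adjusted p was 0.02, which became adjusted p = 0.21 with an estimated correlation. The number that rose was 19 without replicate 1 at 3% sucrose and 20 without replicate 2 at 8% sucrose.

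**Figure D1:**
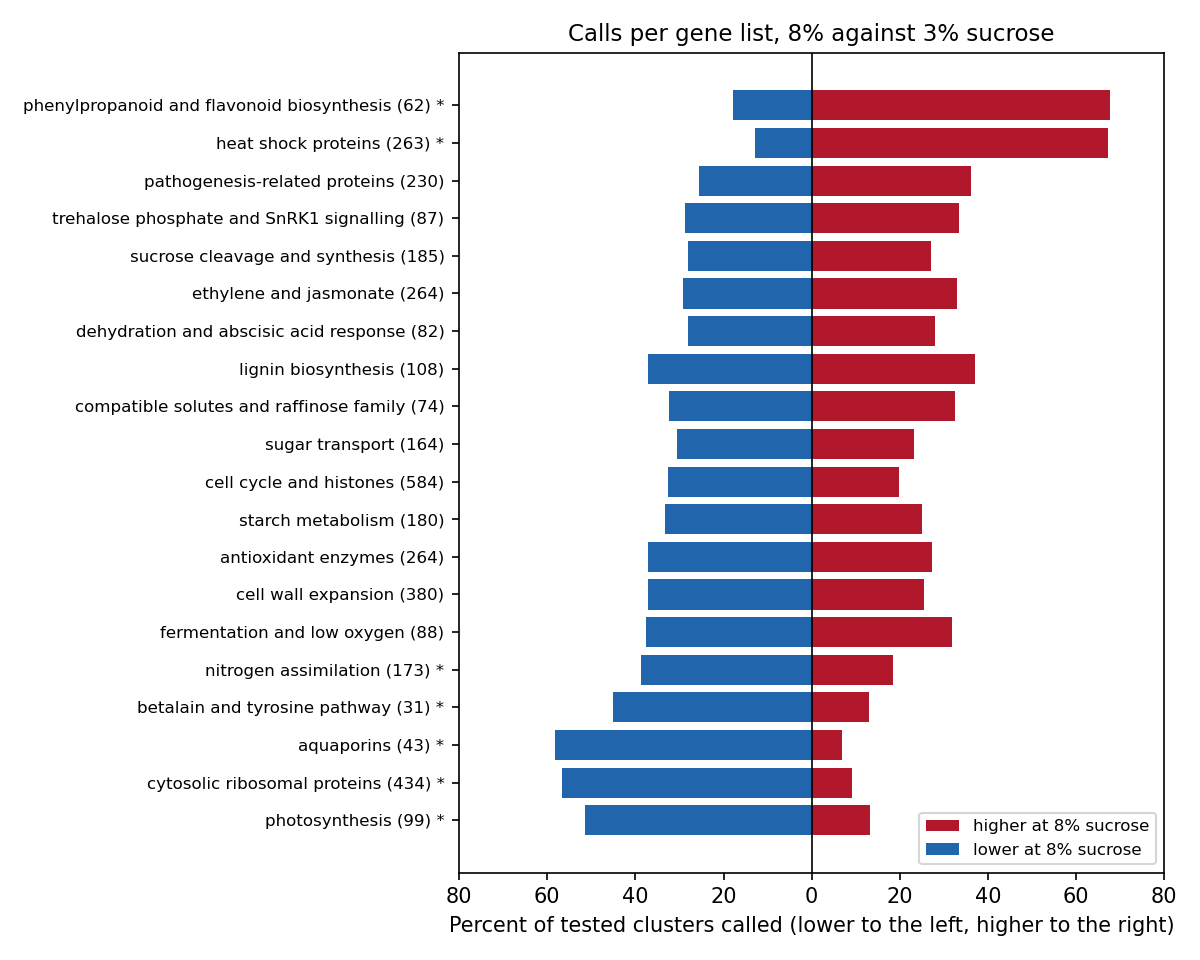
Percent of the tested clusters of each of the 20 gene lists that were called higher (right, red) or lower (left, blue) at 8% sucrose, with the number of tested clusters in parentheses and an asterisk at the 7 lists called by the directional test with the preset correlation. Heat shock proteins lie mostly to the right, with 177 of 263 higher, and cytosolic ribosomal proteins to the left, with 246 of 434 lower.

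In the lists for handling sugar itself clusters went both ways, and none of these lists passed the directional test on clusters. The Gene Ontology terms for starch metabolism, sucrose metabolism and glycolysis, given below, were enriched among clusters that fell. Glucose metabolic process was enriched among those that rose. None of these was called with 1 cluster per hit, where a term left with under 20 clusters was not tested. Of 164 sugar transport clusters 38 rose, 50 fell and 76 did not pass (38 and 50 adjusted over the list alone; list adjusted p = 0.277), yet the summed level went from 5784 ± 190 CPM (SD, n = 3) to 1892 ± 107 CPM (SD, n = 3). The hexose transporter sugar carrier protein C (Cluster-2051.79589), which held most of that sum at 3% sucrose but not at 8% sucrose, fell from 3450 ± 128 to 415.9 ± 20.1 CPM, with a log2 fold change of -3.05 ± 0.05 (SE) and an adjusted p of 4.60e-07. Sucrose transport protein SUC4 (Cluster-2051.96600) rose from 14.54 ± 0.718 to 37.64 ± 2.02 CPM. Of 185 sucrose cleavage and synthesis clusters 50 rose and 52 fell, also when adjusted over the list alone, and 83 did not pass (list adjusted p = 0.957). This pattern also took 50 clusters of 6-phosphofructokinase, of which 8 rose and 12 fell. Hexokinase-1 (Cluster-2051.57700), which phosphorylates glucose, fell from 197.7 ± 6.56 to 34.11 ± 2.43 CPM. A sucrose synthase cluster (Cluster-2051.76798) rose from 35.59 ± 1.20 to 328.5 ± 26.6 CPM, while the 8 clusters of its hit together fell from 1420 ± 37.6 to 775 ± 39.3 CPM.

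Of 180 starch metabolism clusters 45 rose and 60 fell, also when adjusted over the list alone, and 75 did not pass (list adjusted p = 0.277; median log2 fold change -0.20, mean 0.02). Inactive beta-amylase 9 (Cluster-2051.84372) fell from 733.5 ± 12.3 to 212.1 ± 14.1 CPM. A starch synthase 4 cluster (Cluster-2051.87829) had 0 counts at 3% sucrose and 6.561 ± 0.41 CPM at 8% sucrose, at least 79.1-fold higher, but the 26 clusters of its hit together gave a log2 fold change of -0.59. In the list of trehalose phosphate and SnRK1 signalling, which report sugar status inside plant cells, 29 of 87 clusters rose, 25 fell and 33 did not pass (30 and 26 adjusted over the list alone; list adjusted p = 0.792). Trehalose-phosphate phosphatase D, summed over its 9 clusters, rose from 0.266 ± 0.301 to 123 ± 17.9 CPM. A trehalose-phosphate synthase 1 cluster (Cluster-2051.70231) rose from 6 counts over the libraries at 3% sucrose to 1309 counts at 8% sucrose, a log2 fold change of 7.61, while the 10 clusters of its hit together rose from 14.4 ± 0.706 to 48.3 ± 11.9 CPM, a log2 fold change of 1.75. The SnRK1 regulatory subunit gamma-1 (Cluster-2051.75789) fell from 672.3 ± 8.71 to 210.4 ± 9.68 CPM. Of 74 clusters for compatible solutes and the raffinose family 24 rose, 24 fell and 26 did not pass (24 and 27 adjusted over the list alone; list adjusted p = 0.751, direction down, median -0.12, mean 0.23). Galactinol synthase 2 (Cluster-2051.77750), which makes the galactosyl donor for raffinose, rose from 7.98 ± 0.933 to 400.5 ± 29.4 CPM, with a log2 fold change of 5.65 ± 0.12 (SE) and an adjusted p of 5.42e-07. Proline dehydrogenase 2 (Cluster-2051.77788), which breaks proline down, fell from 1115 ± 0.587 to 268.6 ± 19.9 CPM. Hits of 2 enzymes that make proline also fell. Summed by hit, delta-1-pyrroline-5-carboxylate synthase went from 145 ± 4.16 to 89.7 ± 2.86 CPM and pyrroline-5-carboxylate reductase from 64.9 ± 2.83 to 14.6 ± 1.08 CPM.

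**Figure D2:**
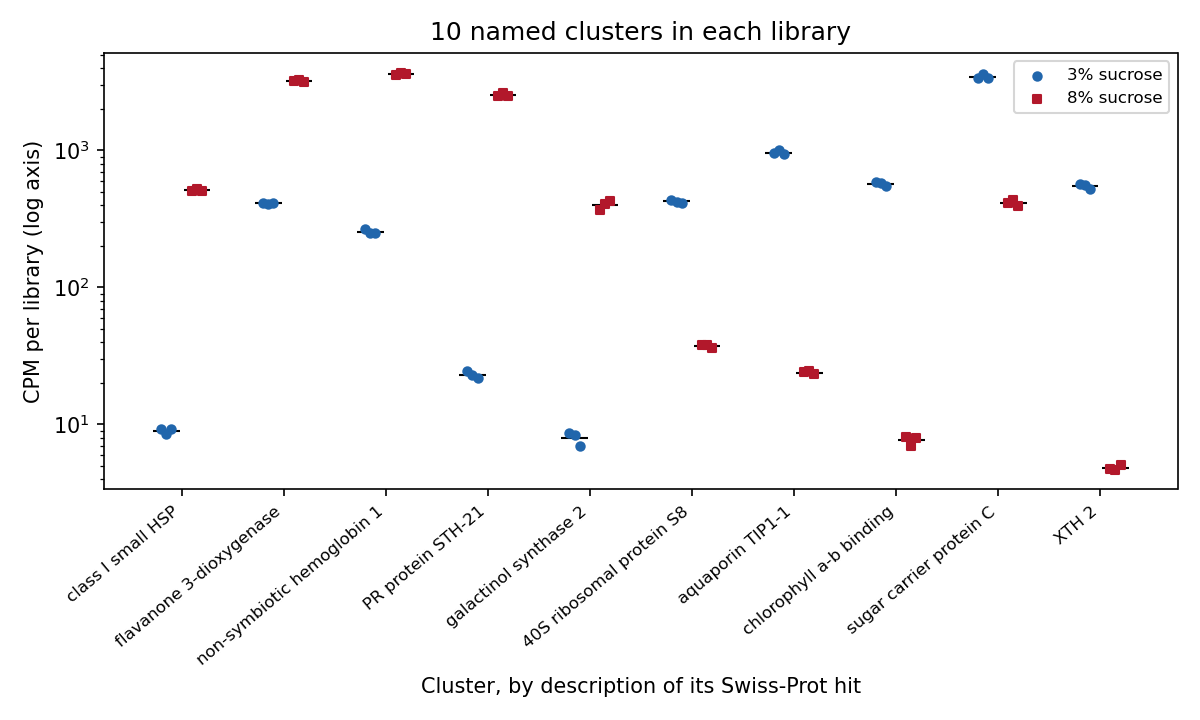
CPM per library on a log axis for 10 named clusters, with circles for the 3 libraries at 3% sucrose, squares for the 3 at 8% sucrose and a black line at each mean. The libraries of one medium do not overlap those of the other in any of the 10 clusters, for example 8.999 against 511.5 CPM (means) for the class I small heat shock protein.

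The stress and hormone lists were also mixed. Of 230 clusters of pathogenesis-related proteins, secreted defence proteins such as chitinases, 83 rose, 59 fell and 88 did not pass (86 and 61 adjusted over the list alone; list adjusted p = 0.277). Their summed level went from 9064 ± 153 CPM (SD, n = 3) to 24300 ± 719 CPM (SD, n = 3). Pathogenesis-related protein STH-21 (Cluster-2051.77433) rose from 23.03 ± 1.36 to 2548 ± 75.1 CPM, with a log2 fold change of 6.79 ± 0.07 (SE) and an adjusted p of 1.51e-07. Chitinase-like protein 1 (Cluster-2051.78297) fell from 300.7 ± 9.41 to 48.39 ± 2.92 CPM, a log2 fold change of -2.64 against -0.74 for the 5 clusters of its hit. Of 264 ethylene and jasmonate clusters 87 rose, 77 fell and 100 did not pass (88 and 77 adjusted over the list alone; list adjusted p = 0.957, direction down, median 0.20, mean 0.52). Summed by hit, ACC synthase and ACC oxidase 5, the last enzymes of ethylene synthesis, rose from 57.7 ± 23.4 to 703 ± 164 CPM and from 28.2 ± 4.18 to 719 ± 66.0 CPM. The ethylene-responsive factor ERF098 (Cluster-2051.42414) rose from 0.6573 ± 0.139 to 50.06 ± 3.47 CPM. An ACC oxidase homolog 1 cluster (Cluster-2051.11502) fell from 150.4 ± 3.16 to 12.04 ± 0.332 CPM, but its hit of 35 clusters gave a log2 fold change of 0.30.

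Of 82 dehydration and abscisic acid clusters 23 rose and 23 fell, also when adjusted over the list alone, and 36 did not pass (list adjusted p = 0.792; median log2 fold change 0.00). The abscisic acid receptor PYL8 (Cluster-2051.54981) rose from 13.84 ± 0.681 to 61.3 ± 3.72 CPM. Summed by hit, the receptors PYL4 and PYL1 fell, from 124 ± 9.31 to 31 ± 1.34 CPM and from 118 ± 1.93 to 16.5 ± 1.01 CPM. The Lea14 homolog, a late embryogenesis abundant protein (Cluster-2051.113914), fell from 226.3 ± 3.62 to 41.08 ± 1.08 CPM. Its log2 fold change was -2.46, against -1.71 for the 7 clusters of its hit. Of 264 antioxidant enzyme clusters 72 rose, 98 fell and 94 did not pass (76 and 102 adjusted over the list alone; list adjusted p = 0.0883). A Cu-Zn superoxide dismutase (Cluster-2051.93183) rose from 4.213 ± 0.193 to 100.9 ± 6.76 CPM and a glutathione S-transferase (Cluster-2051.48467) fell from 290.5 ± 5.33 to 40.05 ± 0.969 CPM. Of 88 clusters for fermentation and low oxygen 28 rose, 33 fell and 27 did not pass (29 and 34 adjusted over the list alone; list adjusted p = 0.751, direction down, median -0.41, mean 0.74). Non-symbiotic hemoglobin 1 (Cluster-2051.79794), an oxygen- and nitric oxide-binding protein, rose from 255.5 ± 10.6 to 3604 ± 75.1 CPM, with a log2 fold change of 3.82 ± 0.05 (SE) and an adjusted p of 2.71e-07. Pyruvate decarboxylase 4 (Cluster-2051.71918) fell from 63.45 ± 2.18 to 13.64 ± 0.824 CPM, and alcohol dehydrogenase, summed by hit, from 3130 ± 78.2 to 1750 ± 52.4 CPM. This pattern also took 34 clusters named for cinnamyl alcohol dehydrogenase and other off-list proteins, of which 18 rose and 4 fell. These off-list clusters make up most of the 28 that rose but few of the 33 that fell. The other members therefore fell more often than they rose, and they were not tested alone.

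Of 380 cell wall expansion clusters 97 rose, 141 fell and 142 did not pass (99 and 142 adjusted over the list alone; list adjusted p = 0.0789). This pattern also took 16 clusters of polygalacturonase inhibitors and receptors, of which 12 rose and 3 fell. Xyloglucan endotransglucosylase/hydrolase 2 (Cluster-2051.10043), which cuts and rejoins wall xyloglucan, fell from 549.2 ± 21.2 to 4.801 ± 0.209 CPM, with a log2 fold change of -6.84 ± 0.07 (SE) and an adjusted p of 1.51e-07. Its relative, protein 23 of the same family (Cluster-2051.78877), rose from 246.5 ± 7.85 to 956.5 ± 37.9 CPM. Of 108 lignin biosynthesis clusters 40 rose, 40 fell and 28 did not pass (41 and 41 adjusted over the list alone; list adjusted p = 0.792, direction down, median -0.11, mean 0.51). A probable cinnamyl alcohol dehydrogenase 1 (Cluster-2051.78602) rose from 78.88 ± 1.01 to 653.2 ± 26.9 CPM, and one described as cinnamyl alcohol dehydrogenase 1 (Cluster-2051.122629) fell from 24.39 ± 0.394 to 0.9036 ± 0.213 CPM, a log2 fold change of -4.75 against -1.88 for the 2 clusters of its hit. Of 584 cell cycle and histone clusters 116 rose, 191 fell and 277 did not pass (114 and 188 adjusted over the list alone; list adjusted p = 0.102). The small chain of ribonucleotide reductase (Cluster-2051.46781), which supplies deoxyribonucleotides for DNA synthesis, fell from 137.8 ± 1.10 to 9.436 ± 0.224 CPM. Summed by hit, a large subunit of this enzyme rose from 128 ± 6.3 to 210 ± 17.3 CPM. A linker histone H1 (Cluster-2051.75797) rose from 60.34 ± 3.78 to 405.3 ± 6.91 CPM, a log2 fold change of 2.75 against 1.23 for the 4 clusters of its hit.

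The directional list test rests on a preset correlation. Splits of the 6 libraries other than the real split gave 3 to 6 called lists each. Those splits mix the media unevenly and keep part of the difference between them. Their counts therefore do not show how many lists are called by chance. With counts summed by Swiss-Prot hit, the antioxidant (adjusted p = 0.012), cell cycle (0.00497), cell wall (0.0207) and starch (0.0041) lists were also called lower. Matched on NR descriptions, the antioxidant (0.0231) and cell wall (0.0317) lists were also called lower. Over the 13 alternatives that used this test the adjusted p ranged from 5.6e-10 to 0.181 for heat shock proteins, from 1.88e-18 to 0.21 for ribosomal proteins and from 3.38e-08 to 0.0442 for photosynthesis. It ranged from 8.99e-05 to 0.141 for the phenylpropanoid list, from 8.99e-05 to 0.21 for aquaporins, from 0.00159 to 0.14 for the betalain list and from 0.000483 to 0.21 for nitrogen assimilation. It ranged from 0.012 to 0.262 for the antioxidant list, from 0.00497 to 0.144 for the cell cycle, from 0.0207 to 0.205 for the cell wall and from 0.0041 to 0.515 for starch.

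The largest rises and falls among abundant clusters were from or to 0 counts, so their folds are lower bounds, set by 3 counts per library. Syntaxin-121 (Cluster-2051.78424), a membrane fusion protein of secretion, held 1346 ± 83.6 CPM at 8% sucrose, at least 16200-fold higher. A cluster with a deacetoxyvindoline 4-hydroxylase hit (Cluster-2051.78833) held 1200 ± 59.3 CPM, at least 14500-fold higher, and a defensin-like protein (Cluster-2051.52825) held 216.9 ± 23.1 CPM, at least 2610-fold higher. A cyclin-dependent kinase G-2 cluster (Cluster-2051.78082) held 141.1 ± 6.55 CPM at 3% sucrose and was at least 1780-fold lower at 8% sucrose. Gibberellin-regulated protein 1 (Cluster-2051.9078) was at least 1480-fold lower and a threonylcarbamoyltransferase of tRNA (Cluster-2051.47633) at least 1110-fold lower. Summed over all clusters of the same Swiss-Prot hit, the log2 fold changes were smaller, at 4.21, 1.5 and 5.79 for those that rose. For those that fell they were -2.21 for the gibberellin-regulated protein, -1.26 for the transferase and 0.42, in the opposite direction, for the kinase. Summed by NR hit, 3 of the 6 stayed at 0 counts in one medium. These were the defensin, with 0 counts at 3% and 24702 at 8% sucrose over 2 clusters, and the gibberellin-regulated protein (12728 and 0) and the transferase (9516 and 0), with 1 cluster each. A sum over 1 cluster is the cluster itself, so for the gibberellin-regulated protein and the transferase this outcome was fixed in advance.

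Of 560 Gene Ontology biological process terms tested, 10 were enriched among the clusters that rose and 14 among those that fell (one-sided Fisher's exact tests with Benjamini-Hochberg adjustment). With 1 cluster per Swiss-Prot hit 4 terms were enriched among those that rose and 15 among those that fell, and 6 of these 19 were among the 24. The terms lowest in p were then metabolic process, with 340 of 721 clusters lower, translation, with 227 of 467, and ribosome biogenesis, with 245 of 511. DNA integration was the strongest, with 211 of 492 clusters higher, or 42.9% against 26.6% of the background, and an adjusted p of 4e-12. Retroelement names were carried by 315 of its 492 clusters, and the term was not called with 1 cluster per hit. Response to stress followed, with 140 of 366 clusters higher, or 38.3%, and an adjusted p of 0.00024. It took in 56 clusters of calmodulin-binding protein 60, a defence regulator, and 48 named as heat shock proteins or endoplasmin. Among clusters that fell, androgen and estrogen metabolic process led with the same 217 clusters, of which 92 fell, or 42.4% against 28% of the background, with an adjusted p of 0.000654. These terms are named for animal hormones, and their clusters here included 25 with a cinnamoyl-CoA reductase hit, a lignin enzyme, 15 with a tetraketide alpha-pyrone reductase hit, an enzyme of pollen wall sporopollenin, and 15 with a 3beta-hydroxysteroid dehydrogenase hit, a steroid enzyme. Among terms for sugar, glycolytic process (104 of 253 clusters, adjusted p = 0.000733), gluconeogenesis (120 of 308, 0.00213), and starch and sucrose metabolic process (167 of 482 each, 0.0375) were enriched among clusters that fell. Glucose metabolic process was enriched among clusters that rose (24 of 48, 0.0286). None of these 5 terms was called with 1 cluster per hit.

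Nearly all counts with an assigned species fell on land plant proteins. By NR hit, 99794 clusters were assigned to land plants, 896 to algae or protists, 1 to a bacterium and 1 to an animal. Yet 1266 clusters with an Escherichia or Shigella Swiss-Prot hit had no NR hit. The NR search may have been limited to plants and algae, which the sources used here do not state. The land plant share therefore does not show how much microbial RNA was present. Land plant hits took 94.21% ± 0.337 (SD, n = 3) of the counts at 3% sucrose and 93.14% ± 0.216 (SD, n = 3) at 8% sucrose, a difference of -1.07 percentage points (exact two-sided permutation p = 0.1). With hits of an E-value under 1e-20 alone the difference was -1.62. Hits to algae or protists took 0.0154% ± 0.00103 (SD, n = 3) and 0.0155% ± 0.00185 (SD, n = 3). Clusters without an assigned species took 5.778% ± 0.336 (SD, n = 3) and 6.847% ± 0.214 (SD, n = 3).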

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

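A signal outside the main comparisons was seen on clusters whose best Swiss-Prot hit is a protein of Escherichia or Shigella and which have no NR hit. There were 1266 such clusters, and together they took a mean of 0.0077% of the counts. Their median was 11 counts over the 6 libraries, which is under 3 counts per library, the limit that a count of 0 allows. The share was 0.00723% ± 0.000508 (SD, n = 3) at 3% sucrose and 0.00817% ± 0.00238 (SD, n = 3) at 8% sucrose, with an exact two-sided permutation p of 0.9. Of these clusters 8 had enough counts to be tested between the media. Their hits were spread over 1115 different proteins.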

How the results depend on the processing

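The count of 46464 changed clusters stayed within 1.5 times of itself under all alternatives but 1. With counts summed by Swiss-Prot hit there were 29502 calls among fewer features, 44769 in place of 85043. Other counts were 46325 with DESeq2 size factors, 47865 with the DESeq2 Wald test, 48223 without a filter, 49449 with the stricter filter and 35646 with land plant hits alone. Leaving out each library in turn gave 41476 to 44614 calls, 7 called lists each time, 20 to 28 terms and a land plant difference of -1.21 to -0.883 percentage points. The number of called lists fell to 1 with an estimated correlation and was 17 with fry, which asks whether a list moves on balance one way and does not set it against other clusters. The land plant difference moved from -1.07 to -1.62 with the stricter E-value, and the cause was not tested.

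Of 552 values of the 46 named clusters under the alternatives 547 kept their direction and their side of the threshold, and 5 reversed, all with counts summed by Swiss-Prot hit. These were the ACC oxidase homolog 1 cluster (Cluster-2051.11502, 0.30), glutamate dehydrogenase B (Cluster-2051.77664, -0.14), starch synthase 4 (Cluster-2051.87829, -0.59), sucrose synthase (Cluster-2051.76798, -0.87) and cyclin-dependent kinase G-2 (Cluster-2051.78082, 0.42). By construction these sums add other clusters of the same protein, which outweigh the named one.

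Whether the replicate numbers pair the samples cannot be told from these libraries. Deviations from the group means correlated at 0.031, 0.005 and 0.014 between libraries of the same number, and replicate 2 at 3% sucrose correlated best with replicate 3 at 8% sucrose, at 0.025. The value of 0.031 was the highest of all pairs. All values were near 0, so they give no sign of pairing and do not exclude it. With the replicate number as a block 38629 clusters, 7 lists and 24 terms were called, and 0 lists changed their call. The median log2 fold change of all tested clusters was 0.19, and 0.29 without a filter. The simulated recovery of 24% at 2-fold holds for 200 changed clusters of 85043 and does not give the share left uncalled here, since the adjusted threshold is less strict when more clusters change. Alternatives meant for a file without counts were not run.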

Other observations

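The families in this part, the tests of the all-or-none clusters as a whole, the named unannotated clusters and the 3 patterns weighed were chosen after the data were seen. The other tests of these patterns were written before their results were seen. Of 14 such families 10 passed the directional test with the preset correlation, and none did with an estimated correlation, where the lowest adjusted p was 0.142. Heat stress transcription factors, which switch on heat shock protein genes, were higher at 8% sucrose, with 34 of 58 tested clusters that rose and 8 that fell (camera adjusted p = 0.000295 over 14 families; adjusted p = 0.142 with an estimated correlation). Summed by hit, HSF30 rose from 283 ± 9.81 to 1860 ± 71.2 CPM and the A-2 factor from 20.4 ± 1.25 to 240 ± 24.2 CPM. The HSF30 and HSF24 hits also belong to the heat shock protein list, so this family is not separate from that list. WRKY factors, regulators of stress and defence, rose in 73 and fell in 34 of 167 clusters (adjusted p = 0.0442; adjusted p = 0.371 with an estimated correlation), with WRKY33 from 161 ± 23.8 to 1260 ± 148 CPM. Pleiotropic drug resistance transporters, which are membrane pumps, rose in 18 and fell in 7 of 27 clusters (adjusted p = 0.0215; adjusted p = 0.266 with an estimated correlation). Of their 3 hits the most abundant rose from 563 ± 59.4 to 10200 ± 406 CPM, and pleiotropic drug resistance protein 3 fell from 349 ± 20.3 to 64.1 ± 3.06 CPM. Wall-associated and lectin receptor kinases rose in 50 and fell in 16 of 104 clusters (adjusted p = 0.0037; adjusted p = 0.228 with an estimated correlation). Retrotransposon polyproteins rose in 315 and fell in 95 of 644 clusters (adjusted p = 0.000295; adjusted p = 0.223 with an estimated correlation).

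Tubulins, the subunits of microtubules, were lower at 8% sucrose, with 25 of 33 clusters that fell and 2 that rose (adjusted p = 2.92e-06; adjusted p = 0.22 with an estimated correlation). The beta-8 chain fell from 1340 ± 54.5 to 173 ± 11.2 CPM. NAC factors fell in 37 and rose in 21 of 77 clusters (adjusted p = 0.0215; adjusted p = 0.228 with an estimated correlation). Efflux transporters of the MATE family fell in 41 and rose in 23 of 98 (adjusted p = 0.0215; adjusted p = 0.142 with an estimated correlation). UDP-glycosyltransferases fell in 32 and rose in 15 of 68 (adjusted p = 0.0215; adjusted p = 0.142 with an estimated correlation), but their summed level went from 1680 ± 39.4 to 1890 ± 45.5 CPM, with the most abundant hit, a putative flavonoid 3-O-glucosyltransferase, from 922 ± 22.1 to 1510 ± 36.2 CPM. Glycolysis enzymes fell in 78 and rose in 40 of 226 (adjusted p = 0.0301; adjusted p = 0.22 with an estimated correlation), with enolase from 3290 ± 71 to 1240 ± 47.6 CPM and cytosolic glyceraldehyde-3-phosphate dehydrogenase the other way, from 3220 ± 127 to 4270 ± 168 CPM. The other 4 families did not pass the directional test. MYB factors rose in 25 and fell in 37 of 122 clusters (adjusted p = 0.155), the mitochondrial respiratory chain in 48 and 76 of 203 (0.155), and DnaJ and BAG co-chaperones in 107 and 75 of 296 (0.433). Proteasome subunits (0.224) rose in 50 and fell in 72 of 204 clusters, and with counts summed by hit 39 of 59 fell and 8 rose. Over both media, the most abundant cluster without an NR or Swiss-Prot hit (Cluster-2051.79917, 381 bp) fell from 8530 ± 663 to 258 ± 4.77 CPM. Of the next in abundance, Cluster-2051.78215 fell from 7770 ± 503 to 672 ± 10.2 CPM and Cluster-2051.78641 from 1980 ± 40.3 to 1060 ± 50 CPM. Cluster-2051.79229 rose from 1960 ± 139 to 5970 ± 379 CPM, the highest of these at 8% sucrose. The long cluster resembling ribosomal RNA (Cluster-2051.78244, 6998 bp) fell from 14500 ± 837 to 6750 ± 2600 CPM.

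The lower level of cytosolic ribosomal protein clusters was set against technical explanations. A bias with cluster length is argued against, since the median log2 fold change was still -1.51 (95% interval -1.64 to -1.32) after the trend with length was removed. Reads moved to other clusters of the same protein are argued against by the counts summed by hit, with a median of -1.71 (-1.88 to -1.54) relative to all features. The abundance of the clusters is argued against too, as the list median lay at percentile 0 of 10000 random lists of matched abundance. A difference between the cultures that goes with the medium, biological or in handling, may remain and was not tested, because all libraries of one medium share it.

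The higher level of heat shock protein clusters was tested in the same way. The median log2 fold change was 1.54 (95% interval 1.34 to 1.75) after the trend with length was removed, and 1.64 (1.15 to 2.24) relative to all features with counts summed by hit. The list median lay at percentile 100 of 10000 random lists of matched abundance. Length, reads moved between clusters of a protein, and abundance are therefore argued against as the cause. A response to sucrose may be the cause, as may a difference in cell material behind the letters R and Y of the titles or any stress that differed between the cultures at harvest, and none of these was tested.

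There were 988 clusters with at least 300 counts in one medium and 0 in all 3 libraries of the other, 505 of them only at 8% and 483 only at 3% sucrose, together 0.705% and 0.521% of the counts. Reads of one gene divided between clusters could give such a pattern, for example when the media differ in which allele or assembled form takes the reads. With an NR hit taken as the gene, this is argued against as the whole cause. In 263 of the 794 clusters with an NR hit, or 33.1% (95% interval 29.9 to 36.5), the hit held too few reads. All clusters of the hit together then held under 50% as many reads in the other medium. The 263 include 68 clusters whose hit has no other cluster, for which this outcome was fixed in advance, so they add nothing to the argument. Clusters of one gene can carry different NR hits, which this test cannot see. The interval also treats clusters that share a hit as independent. For the 531 outside the 263, the remaining clusters of the hit changed in the opposite direction in 197, or 37.1% (33 to 41.4). Reads moved within a gene of constant level would give an opposite change. The level of a gene can change too, so a change in the same direction does not exclude divided reads. This explanation stays open for all 531. Whether the cultures of the media differ in genotype was not tested, and this explanation may hold for any part of the 988.

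The 6 libraries can be split into 3 and 3 in 10 ways, the real split included, which is too few for a share under 0.05. The real split gave 46464 clusters, 7 lists and 24 terms. The highest of the other splits gave 0 clusters, 6 lists and 0 terms. In every other split, each set of 3 holds libraries of both media. The difference between the media then adds to the spread within each set, which works against calling clusters, and the terms rest on those calls. The media are mixed unevenly, so part of their difference also stays between the sets and can give called lists. These splits therefore cannot show how many clusters, lists or terms would be called by chance.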
